A study of Homo sapiens with 2 samples.

How the data were processed

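Bronchoalveolar lavage cells of 2 people were profiled by 3′ droplet single-cell RNA sequencing, 1 library each, and the source label gives the group of each library. Per the labels, cells were thawed, kept overnight in culture medium, sorted for live cells by dye exclusion, and about 5000 were loaded for a target of 3000, with reads of 75 bp. The numbers of barcodes in the files, 5402 and 5139, lie above both. Per the submitters' processing notes, Cell Ranger 3.1.0 and Seurat 4.0.1 were used with the GRCh38 build. The notes list only these names, and settings are not given in the sources used here.

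The deposited matrices hold counts, whole UMIs per gene and barcode for 33538 genes, without normalization. A deposited table lists 7412 CD3 cells with a cell type cluster, UMI and gene totals, and percent of mitochondrially encoded UMIs as the authors computed it. Its barcodes were mapped to the 2 libraries by their sample labels, and all 868 and 1510 listed cells were found. Their UMI totals were identical to those of the matrices for 63.8% and 71.3% of the cells and differed by at most 8 and 7 UMIs. The other 10 sample labels of the table, with 5034 cells, match no sample used here and were not used. The table types the exposed library as BeS, an abbreviation that neither it nor the labels spell out. It is in use for beryllium sensitisation, so this library is possibly from a sensitised person, which the sources used here do not settle, and the group name of the labels was kept.

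The choices named as main below, the gene lists, the cell type markers and the rule for named genes were made before the data were examined. Barcodes with at least 500 UMIs, at least 200 genes and under 20% mitochondrially encoded UMIs were kept, which removed 8 and 2 barcodes by the minimum and 752 and 211 by the mitochondrial limit. Scrublet marked 2 and 0 barcodes as doublets, under the 0.5% set as the least for a working call, so none were removed, against the removal planned, and leaving out the 5% with the highest scores was added as an alternative. Both libraries were clustered together without integration (scale 10000, 2000 variable genes, 30 components, 15 neighbours, Leiden resolution 1, seed 1). T cells, their subsets and NK cells were taken from the deposited table, and the other classes were named from the markers. Macrophages were compared as 1 class, as planned, since a split into alveolar and monocyte-derived cells can differ by library. Cluster 8, led by cell cycle genes, was left out of it after the clusters were seen, and cluster 9, which mixed markers of B, plasma and dendritic cells, stayed unnamed.

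Counts were summed over all cells of a class in each library and scaled to CPM, the count of a gene over all counts of the sum times 1e6. With 1 library per group no test was made. Genes with at least 50 UMIs and 50 CPM in at least 1 library and a ratio of at least 2 were counted as at least 2-fold apart, a rule of size. Members of the lists were counted as higher or lower at a log2 difference of at least 1 with 5 CPM added, without that detection limit, so a member with few UMIs can pass 2-fold by ratio and not be counted. The genes named are taken from the 12 highest and 12 lowest log2 differences of each comparison that keep their direction as a mean of per-cell shares and after thinning, and up to 4 extreme members of each list. Further list members are named as examples and were chosen after their values were seen. Genes whose level can follow a common germline deletion or variant, sex-linked genes, HLA genes other than HLA-DRA, antigen receptor segments, immunoglobulin constant genes and unnamed loci are not reported here. A few more genes of this kind were left out of the text after the values were seen, but stay in the counts. Sums have exact Poisson intervals, ratios exact intervals conditional on the total, and shares exact Clopper-Pearson intervals, all at 95% and for counting error only. A count of 0 was given the floor of 3 counts. Library depth sets the precision: a T cell sum held 1322470 or 2698783 UMIs, a macrophage sum 53175889 or 49003927.

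The gene lists were Th1 and type 1 cytokines, Th17 and Th2, regulatory T, inhibitory receptors, follicular helper, tissue residency, naive, cytotoxic, T cell activation, proliferation, interferon, metallothioneins, alveolar macrophage identity, monocyte-derived, inflammatory, granuloma, antigen presentation, lipid handling, oxidative stress, heat stress, ribosomal protein, mitochondrially encoded and red cell. For each, the median log2 difference of members with at least 20 UMIs over both libraries was set as a percentile among 10000 random lists of the same size matched on mean expression. A list at or below percentile 2.5 or at or above 97.5 is called outside the random range, which describes these libraries. Several members stand in more than 1 list. The free RNA share was set by genes of the other main class, and the profile of the whole library, scaled to it, was subtracted. A gene with fewer counts than its scaled profile was left without counts, not negative. Log2 differences after subtraction can therefore be inflated for genes with few UMIs in either library. Gene positions were read from a GENCODE release 29 annotation of GRCh38, whose identifiers match those in the files for the genes given.

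Steps were tested on simulated data made from the real means and depths, with 200 genes at known folds. The rule of size called 94% of genes at 2.5-fold in T cells, 94% in CD4, 92% in CD8 T cells and 100% in macrophages, and 2%, 0%, 10% and 0% at 1.5-fold. Of unshifted lists, 5%, 4%, 6% and 6.5% lay outside the random range, and 50, 50, 49 and 50 of 50 lists shifted by 0.5 were called. Simulated free RNA of 10% and 30% was found as 10.0% and 29.7%, with its profile given and the marker genes absent from the simulated T cells. In the data neither is known, so the accuracy of the shares estimated there was not tested. Alternatives were other mitochondrial, depth and detection limits, cluster resolutions, clustering each library alone, T cells from clusters, other scalings, pseudocounts of 1 and 20, means of per-cell shares, thinning, removal of high doublet scores and subtraction of free RNA. Work was done in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5 (its scrublet function for doublets), anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9.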

Results

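Bronchoalveolar lavage washes cells out of the air spaces of the lung, mostly macrophages and lymphocytes. The data are 2 lavage libraries of droplet single-cell RNA sequencing, 1 from a beryllium-exposed person and 1 from a person with chronic beryllium disease (CBD), a granulomatous lung disease in which CD4 T cells recognise beryllium. The exposed library held 5402 barcodes and 61258148 UMIs (unique molecular identifiers, each counting 1 captured transcript), with a median of 12338 per barcode, and the CBD library held 5139 barcodes and 55770395 UMIs, with a median of 8521. Of these, 4650 and 4928 barcodes were analysed. Each group is 1 library without replicates, so each difference below is between these libraries, its size could not be set against a spread between donors, and no test was made. Intervals are 95% exact intervals and cover counting error only. Log2 differences are CBD minus exposed, with 5 CPM (UMIs of a gene scaled to the same total in each sum) added to each value. Members of a gene list are counted as at least 2-fold higher or lower by this log2 difference, at 1 or more either way, and single genes outside the lists by the plain ratio.

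T cells and NK cells took a larger share of the CBD library, and macrophages a smaller one. T cells listed in the deposited cell table made up 836 of 4650 barcodes in the exposed library (18.0%, 16.9 to 19.1) and 1427 of 4928 in the CBD library (29.0%, 27.7 to 30.2). Macrophages made up 72.9% (71.6 to 74.1, 3388 barcodes) and 58.1% (56.7 to 59.5, 2863 barcodes). NK cells, which kill without a T cell receptor, were at 0.667% (0.453 to 0.945, 31 cells) and 1.62% (1.29 to 2.02, 80 cells), and dendritic-like cells at 0.817% (0.579 to 1.12) and 1.40% (1.09 to 1.77), an order that turned at resolution 2 (1.91% and 1.68%), with at least 1000 UMIs and 500 genes (2.39% and 2.17%) and under 10% mitochondrially encoded UMIs (1.69% and 0.427%). Proliferating macrophage-like cells, kept apart from the macrophages, were at 2.47% (2.05 to 2.96) and 1.2% (0.913 to 1.54). Barcodes that clustered with lymphocytes without being in the deposited table were at 3.59% and 7.75%, with medians of 788 and 769.5 UMIs. The shares of T cells and NK cells, both taken from that table, thus depend on its limits. With T cells named from clusters and markers alone their shares were 21.8% and 35.1%, but these include barcodes of uncertain identity. The lymphocyte-clustered barcodes outside the table held 441 and 4 UMIs of the epithelial marker SCGB1A1, beside 88 and 322 of the T cell marker CD2. Cluster 6, with 76 exposed and 521 CBD barcodes, was led by the macrophage markers APOC1 and MRC1 when set against the listed lymphocytes. Cells were sorted for live cells before loading, and such a sort can set these shares.

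**Figure D1:**
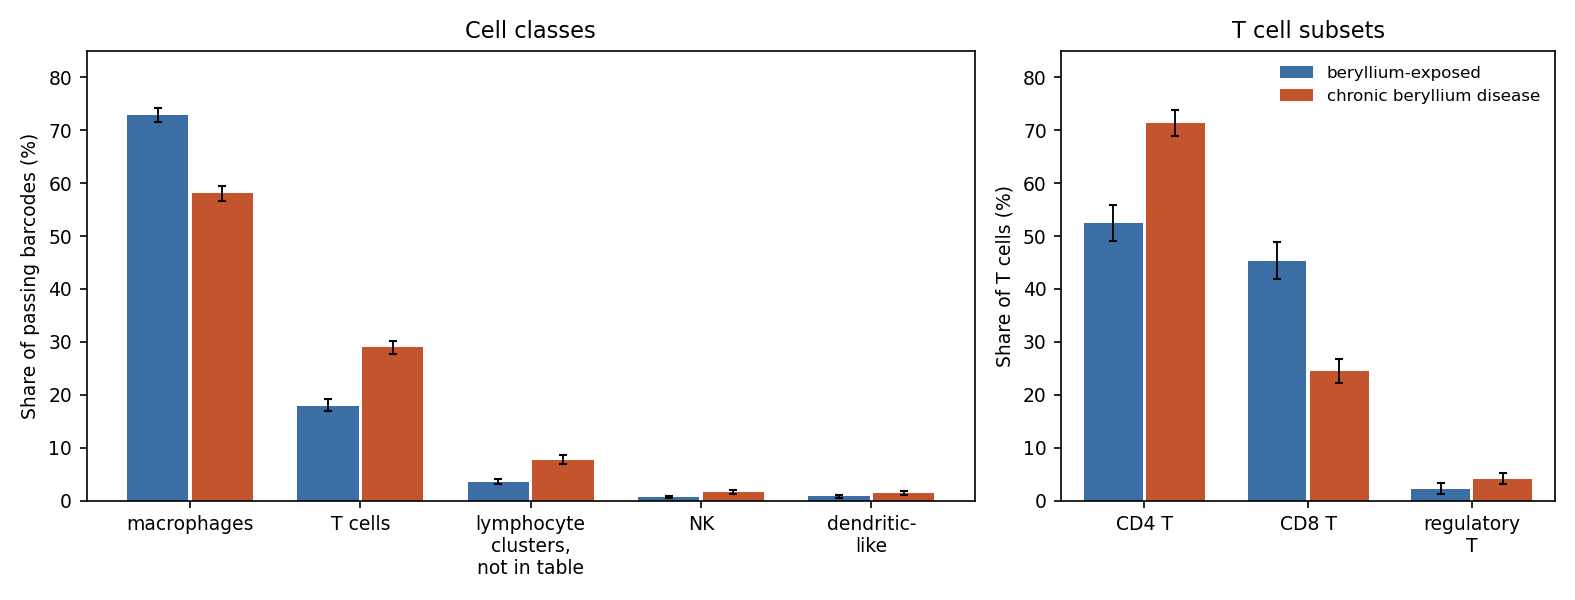
Bars give the share of passing barcodes in 5 classes (left) and the share of T cells in 3 deposited subsets (right), in percent, for the exposed library (blue) and the CBD library (orange). Error bars are 95% exact binomial intervals. T cells were 18.0% against 29.0% of barcodes, and CD4 T cells 52.5% against 71.4% of T cells.

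CD4 T cells, the helper subset, were a larger part of the T cells in the CBD library. Among deposited T cells they made up 52.5% (49.1 to 55.9) in the exposed library and 71.4% (69.0 to 73.7) in the CBD library. Cytotoxic CD8 T cells made up 45.3% (41.9 to 48.8) and 24.5% (22.3 to 26.8), and regulatory T cells 2.15% (1.28 to 3.38) and 4.06% (3.1 to 5.22). As a share of all barcodes, CD8 T cells differed little, at 8.15% (7.38 to 8.97) and 7.10% (6.40 to 7.86), whereas CD4 T cells were at 9.44% (8.62 to 10.3) and 20.7% (19.6 to 21.8). Counting each cell's own CD4 against CD8A and CD8B UMIs gave lower shares of CD4 cells, 15.9% of 384 and 62% of 400 cells that could be assigned, in the same order. CD4 was also a macrophage transcript (115 and 107 CPM in macrophages), and free RNA was estimated at 12.9% and 31.6% of T cell UMIs.

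T cells of the CBD library had less RNA of heat shock and metallothionein genes and of GNLY, XCL1, XCL2 and KLRC1, and more of GZMH and NCR3. GNLY, which encodes the pore-forming granule protein granulysin (chromosome 2, 85685175 to 85698854, GRCh38), was at 1106 CPM (1050 to 1164) in the exposed and 154 CPM (140 to 170) in the CBD library, 7.18-fold lower (6.43 to 8.02). Values for all T cells mix the subsets, whose shares differed between the libraries, and GNLY was 3.46-fold lower (2.33 to 5.16) within CD4 and 4.66-fold lower (4.15 to 5.25) within CD8 T cells. Each subset is itself a mix of deposited clusters, which also differed between the libraries. The lymphoid chemokines XCL1 (147 and 14.8 CPM, 9.90-fold, 7.01 to 14.3) and XCL2 (log2 −2.62), and KLRC1, an inhibitory NK receptor (log2 −2.47), were lower as well. GZMH, a granule protease (chromosome 14, 24606480 to 24609699), was at 175 CPM (154 to 200) and 473 CPM (447 to 499), 2.70-fold higher (2.34 to 3.11), and NCR3, an activating NK receptor, at 13.6 CPM (8.07 to 21.5) and 64.1 CPM (54.9 to 74.4). The T cells came from different clusters: 86.6% of the exposed cells lay in cluster 0, which was mostly of that library, and 73.7% of the CBD cells in cluster 5 and 14.9% in cluster 6, which were mostly of the other. They were sums over 1322470 UMIs in the exposed and 2698783 in the CBD library, with medians of 1521.5 and 1872 UMIs per cell.

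Of 2772 genes past the detection limit in T cells, 263 were at least 2-fold apart, 182 higher and 81 lower in the CBD library. Among the 182 higher genes, 162 were more abundant in macrophages than in T cells and 15 more abundant in T cells. The 12 highest were all of the macrophage kind, among them IGFBP2 (12 and 313 UMIs, log2 3.1), the macrophage chemokine CCL18 (105 and 1511 UMIs, 7.05-fold, 5.78 to 8.68), the esterase CES1 (68 and 954 UMIs, log2 2.67), S100A13 (2.53), TNFAIP2 (2.32), TNFSF13B (2.24), IGSF6 (2.23), C2 (2.13), ANPEP (2.10) and S100A8 (2.06). CCL18 was at 692 and 1767 CPM in macrophages. Macrophage markers were found in 834 of 836 exposed and in all 1427 CBD T cells, at a median of 0.366% and 0.949% of the cell's UMIs, and free RNA was estimated at 12.9% and 31.6% of T cell UMIs. With the free RNA subtracted, 184 genes were at least 2-fold apart, 91 higher and 93 lower, and 52 of the 162 were still at least 2-fold higher. Without mitochondrially encoded and ribosomal protein genes in the total, 313 were, 177 higher and 136 lower.

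Most of the 15 higher genes that were more abundant in T cells fall outside the rule for named genes, and these were chosen after their values were seen. They included NCR3 (log2 1.89), the long non-coding RNA MIR4435-2HG (29 and 237 UMIs, log2 1.79), the homeobox gene HOXB2 (33 and 242 UMIs, 1.66), GZMH (1.40), CRIP1 (623 and 2593 UMIs, 1.02), the interferon-induced GTPase GBP5 (97 and 415 UMIs, 1.02) and TNFRSF18, which encodes the costimulatory receptor GITR (70 and 301 UMIs, 1.01). Of the 81 lower genes, 68 were more abundant in T cells, and 49 of these stayed at least 2-fold lower after subtraction.

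Heat shock and immediate early genes were lower in T cells of the CBD library as a group. All 17 members of that list were measured, 12 were at least 2-fold lower and 0 higher, and the median log2 difference was −1.46, below the range of random lists matched on expression (percentile 0). HSPA6, a strictly inducible heat shock gene, was at 70.3 CPM (56.8 to 86.2) and 4.08 CPM (2.03 to 7.29), 17.3-fold lower (9.21 to 35.8). HSPA1B was 5.92-fold lower (504 and 85.2 CPM) and the co-chaperone DNAJB1 5.40-fold lower (540 and 100 CPM). HSPA1A (log2 −2.02), JUNB (−1.79), IER2 (−1.72), FOSB (−1.64), FOS (−1.41) and JUN (−1.30) went the same way, as did GADD45B (−2.22) and NR4A1 (−2.16) outside the list. HSPA1A and HSPA1B (chromosome 6, 31815464 to 31817946 and 31827735 to 31830255) are nearly identical, so the split of counts between them is uncertain. In macrophages of the same libraries the list's median was 0.21, with HSPA1B at 1.25. Per the labels, the cells had been thawed and kept in culture medium overnight before the sort.

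**Figure D2:**
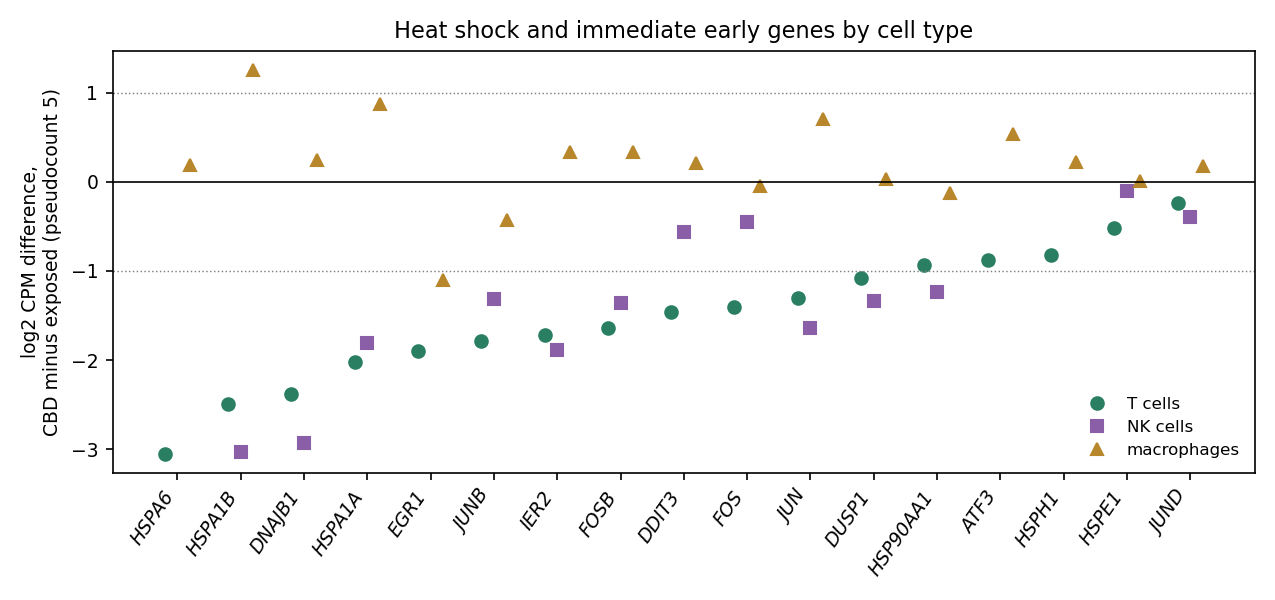
Each point is the log2 CPM difference (CBD minus exposed, pseudocount 5 CPM) of 1 gene of the heat and immediate early list in T cells (circles), NK cells (squares) and macrophages (triangles), for genes with a UMI in both libraries. Dotted lines mark a 2-fold difference. T cell points lie below 0, HSPA6 lowest at −3.05, whereas macrophage HSPA1B was at 1.25.

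Metallothioneins, small proteins that bind zinc and other metals, were lower too. MT1X (chromosome 16, 56682424 to 56684196) was at 638 CPM (596 to 683) and 83.4 CPM (72.8 to 95), 7.65-fold lower (6.60 to 8.91). MT2A was at 1777 and 416 CPM (log2 −2.08) and MT1E at −2.02, and the split of counts among these near-identical genes is uncertain. Of 11 measured members of the metallothionein and metal response list, 4 were at least 2-fold lower, and 3 were higher, FTL (1.31), FTH1 (1.02) and HMOX1 (1.02), which are abundant in macrophages. The list's median was −0.59 (percentile 0).

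The regulatory T list had a higher and the tissue residency list a lower median in all T cells, whose subset shares differed. The regulatory T list had 12 measured members and a median of 0.76 (percentile 100), with ENTPD1, an ectonucleotidase that macrophages also express (9 and 123 UMIs, log2 2.10), and TNFRSF18 at least 2-fold higher. Regulatory T cells, 2.15% and 4.06% of T cells, are in this sum. FOXP3, their transcription factor, was at 0.64 (20 and 71 UMIs, and 2 and 26 in CD4 T cells), BATF at 0.79 and IL2RA at 0.66. With the free RNA subtracted the list's median was 1.01, with 6 members higher. The tissue residency list had 11 measured members and a median of −0.40 (percentile 0.02), with the early activation and retention receptor CD69 (1215 and 449 CPM, log2 −1.42) and the transcription factor ZNF683 (172 and 79 UMIs, −1.98) lower, RGS1 at −0.96, RUNX3 at −0.93, ITGA1 at −0.45, ITGAE at 0.33 and CXCR6 at 0.65. Its median was −0.23 in CD4 and −0.18 in CD8 T cells. In all T cells it was −0.16 (percentile 1.98) after subtraction. Ribosomal protein genes had a median of −0.44 over 16 members (percentile 0.07).

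The type 1 helper list, which holds the cytokine genes central to granulomas, lay within the random range in T cells, with a median of −0.07 over 14 members (percentile 6.25). IFNG, encoding interferon gamma, was at 503 CPM (465 to 543) and 477 CPM (451 to 504), a ratio of 0.948 (0.863 to 1.04). TNF was lower (216 and 110 CPM, log2 −0.94), the chemokine receptor CXCR3 was at 0.71 and CCL3 at 0.71, and EOMES was higher (11 and 74 UMIs, 1.28). The cytotoxic list had 14 members and a median of −0.02 (percentile 17.0), with 3 members at least 2-fold higher, FCGR3A (1.60), GZMH and ZEB2 (1.30), and 3 lower, GNLY, KLRD1 (−1.13) and KLRK1 (−1.03). In CD8 T cells, a smaller part of the CBD T cells, KLRD1 was at −0.44 and KLRK1 at −0.64, and in CD4 T cells KLRD1 was at −0.90. FCGR3A was also a macrophage gene. The inhibitory receptor list (12 members, median 0.11, percentile 29.4), the follicular helper list (7, −0.07, 7.98), the naive list (11, 0.20, 63.8), the proliferation list (10, 0.08, 32.7) and the mitochondrially encoded list (10, −0.09, 35.5) were within the random range.

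The Th17 and Th2 list had GATA3 and KLRB1 both at −0.84, and its median over 7 members was −0.16 (percentile 4.28), within the random range. The T cell activation list (14 members) had a median of 0.44 (percentile 99.3), with the class II invariant chain CD74 (1.10) and EGR2 (1.04) higher and CD69, ICOS (−1.02) and EGR1 (−1.90) lower. Among T cells under 10% mitochondrially encoded UMIs it was 0.34, within the random range.

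Lists of genes that macrophages express strongly were higher in CBD T cells, where the free RNA share was larger. Antigen presentation had a median of 0.92 over 15 members (percentile 100), with CIITA at 1.86, CD86 at 1.74 and HLA-DRA at 0.92, and 0.28 (percentile 90.5) after subtraction. The oxidative stress list was at 0.64 (10 members, percentile 99.9), with TXN at 1.05, and at −0.08 (8.51) after it. The interferon list was at 0.40 (20 members, percentile 99.6; 0.30 and within the range under 10% mitochondrially encoded UMIs), with 6 members at least 2-fold higher and 1 lower, CXCL10 at 2.44 (6 and 126 UMIs), IFI27 at 1.70 and IFI44L at −2.06, and at −0.20 (percentile 0.07) after it. None of the red cell list was measured in T cells. Across the 17 lists measured in T cells, 5 medians lay above and 4 below the random range.

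**Figure D3:**
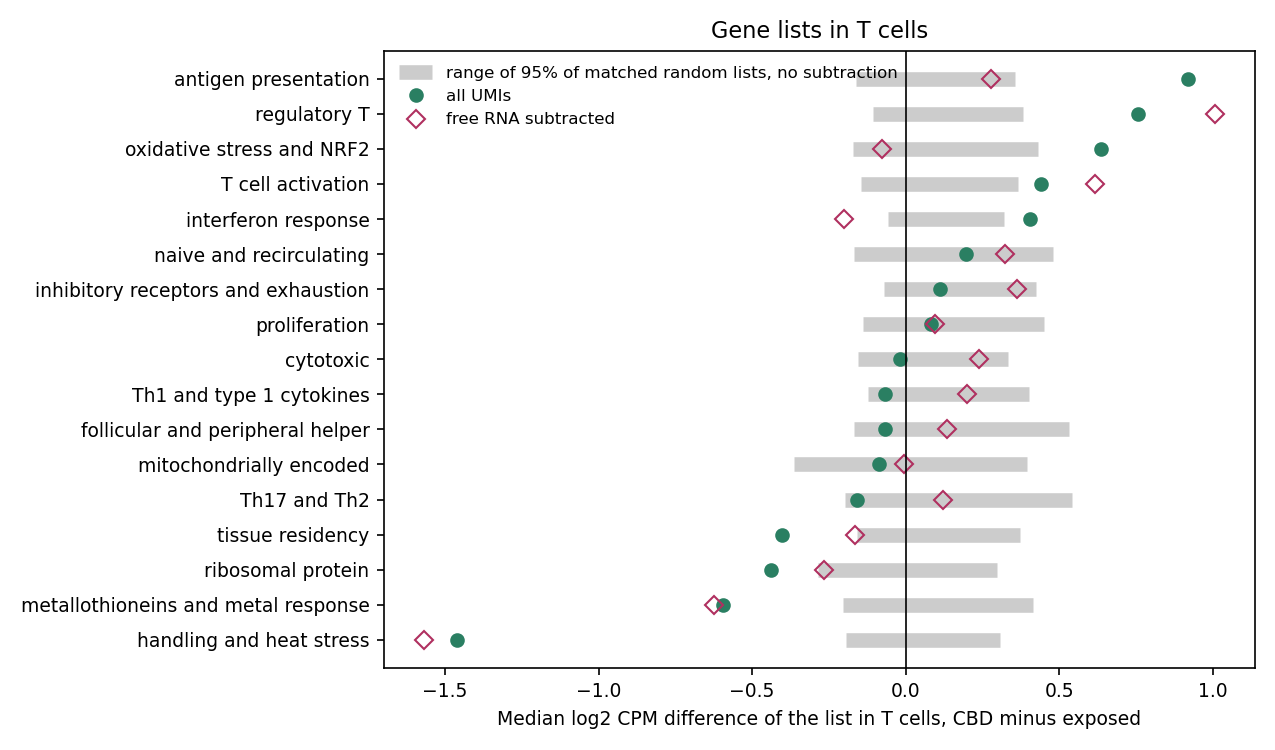
For 17 gene lists in T cells the horizontal axis gives the median log2 CPM difference, CBD minus exposed, from all UMIs (filled circles) and with the free RNA subtracted (open diamonds). Grey bars hold 95% of matched random lists. Heat stress genes stayed lower (−1.46 and −1.57), while the interferon list was at 0.40 and −0.20.

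For shares of T cells with a UMI of a named gene, each cell was thinned to 1500 UMIs, which left 442 exposed and 1023 CBD cells and left out 394 and 404. CD69 was seen in 73.3% (68.9 to 77.4) of exposed and 42.3% (39.3 to 45.4) of CBD T cells, against 4.73% and 4.48% of macrophages, and unthinned in 70.8% and 48.2% of T cells. TNF was seen in 21.7% (18.0 to 25.9) and 12.6% (10.6 to 14.8), against 2.26% and 5.96% of macrophages, and unthinned in 20.3% and 16.0%. The costimulatory receptor ICOS was seen in 10.4% (7.72 to 13.6) and 4.59% (3.39 to 6.06), against 3.06% and 2.03%, and unthinned in 11.1% and 6.03%. CXCR3 was seen in 15.4% (12.1 to 19.1) and 20.1% (17.7 to 22.7), against 0% (0.0892% at a floor of 3 cells) and 0.245%, and unthinned in 13.4% and 23.8%. IFNG was seen in 31.0% (26.7 to 35.5) and 38.2% (35.2 to 41.3), against 0.149% and 1.40%, and unthinned in 30% and 39.0%. Its CPM ratio was 0.948 in all T cells, below both 0.974 in CD4 and 1.15 in CD8 T cells, as the subset mix differed, so no order was read. Over the 22 named genes, 14 had the larger share in the CBD library. Median depth was 1521.5 and 1872 UMIs in T cells and 15459.5 and 17587 in macrophages.

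The CD4 T cells, described as the cells that drive the disease, had more RNA of the granzyme genes GZMB and GZMH in the CBD library, with IFNG at about the same CPM, while the cytotoxic list as a whole lay within the random range. GZMB was at 14.6 CPM (7.0 to 26.8) and 79.9 CPM (67.6 to 93.8), 5.48-fold higher (2.90 to 11.7), and GZMH at 75.9 CPM (56.7 to 99.5) and 285 CPM (261 to 310), 3.75-fold higher (2.82 to 5.09). After thinning, GZMB was seen in 1.32% (0.273 to 3.81) and 7.26% (5.42 to 9.48) of CD4 T cells, against 0.0595% and 0.701% of macrophages, and unthinned in 1.14% and 8.15%. NCR3 was 9.37-fold higher (4 and 102 UMIs, 3.55 to 35.0), and TBX21, the master transcription factor of type 1 helper cells, 3.77-fold higher (4 and 41 UMIs, 1.36 to 14.5). IFNG was at 429 and 418 CPM, a ratio of 0.974 (0.850 to 1.12). Free RNA, estimated at 12.9% and 32.1% of these UMIs, lowers the CPM of a T cell gene more in the CBD library. A like CPM is thus not a like level in the cells' own RNA.

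In CD4 T cells 279 of 2622 genes were at least 2-fold apart, 222 higher and 57 lower, over 685302 and 1864906 UMIs. Of the 222, 189 were more abundant in macrophages, 75 of these still 2-fold after subtraction of the free RNA (12.9% and 32.1% of UMIs), and 22 were more abundant in T cells. With the free RNA subtracted 188 genes were at least 2-fold apart, 127 higher and 61 lower. The highest were IGFBP2 (4 and 220 UMIs, log2 3.50), CES1 (2.89), S100A13 (2.80), CCL18 (2.74), S100A8 (2.55), NCR3 (2.46), TNFSF13B (2.42), IGSF6 (2.40) and CXCL10 (4 and 94 UMIs, 2.35), of which NCR3 is the T cell gene. Among the lowest were XCL1 (73 and 13 UMIs, −3.22), MT1X (−3.16), DNAJB1 (−2.42), MT2A (−2.37), HSPA1B (−2.35), MT1E (−2.29), NR4A1 (−1.98) and HSPA1A (−1.92).

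Among the lists in CD4 T cells, heat stress had a median of −1.47 (17 members, 12 lower, percentile 0) and metallothioneins −0.57 (11 members, 5 lower, 2 higher, percentile 0.01). The regulatory T list was at 0.81 (9 members, percentile 99.8, 0.65 and within the random range after thinning). Cytotoxic genes were at 0.30 (13 members, 4 higher, 1 lower, percentile 90.1), and after subtraction at 0.44 (percentile 98.1). The type 1 helper list was at 0.34 (12 members, 3 higher, 0 lower, percentile 91.0), and after it at 0.61 (percentile 99.8), with TBX21 (1.32), EOMES (1.24) and CCL3 (1.04) higher and TNF at −0.61. Residency genes were at −0.23 (10 members, percentile 1.29), with CD69 at −1.36 and RGS1 at −1.38, and at 0.03 (23.5) after it. Antigen presentation was at 0.94 (percentile 100) and at 0.23 after it, oxidative stress at 0.78 (99.9) and at 0.13, and the interferon list at 0.33 (96.8) and at −0.53 (percentile 0). T cell activation was at 0.58 (13 members, percentile 99.3), with 1 member higher (CD74, 1.07) and 4 lower, among them ICOS (−1.49) and EGR1 (−2.03), and at −0.10 over members with at least 50 UMIs. Ribosomal protein genes were at −0.51 (percentile 0.05), Th17 and Th2 at −0.26 (1.23, within the range over members with at least 50 UMIs) and inhibitory receptors at −0.11 (2.20, and 0.14 after subtraction). The follicular (−0.02), naive (0.09), proliferation (−0.02) and mitochondrially encoded (0.01, and −0.02 scaled by the median ratio) lists were within the random range.

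CD8 T cells of the CBD library, taken as a sum, had more GZMH and GZMK and less GNLY. The sum held 201 (exposed) and 121 (CBD) cells of deposited cluster CD8_7, 120 and 85 of CD8_8, and 58 and 144 of CD8_9. These genes were not compared within the clusters, so a different mix of clusters cannot be told apart from a different level in the cells. GZMH was at 303 CPM (261 to 351) and 1056 CPM (981 to 1134), 3.48-fold higher (2.95 to 4.12), and GZMK, a granzyme of memory cells, at 163 CPM (133 to 199) and 409 CPM (363 to 459), 2.5-fold higher (1.98 to 3.18). GNLY was at 2362 CPM (2240 to 2489) and 506 CPM (455 to 562), 4.66-fold lower (4.15 to 5.25). After thinning, GZMK was seen in 11.3% (7.28 to 16.4) and 27.5% (22.5 to 33.0) of CD8 T cells, against 0.0595% and 0.596% of macrophages, and unthinned in 11.6% and 31.7%. IFNG was at 622 and 715 CPM, a ratio of 1.15 (1.0 to 1.32), and was seen in 36.3% (29.7 to 43.3) and 51.0% (45.2 to 56.8) after thinning, against 0.149% and 1.40% of macrophages, and unthinned in 35.1% and 55.4%.

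In CD8 T cells 252 of 1965 genes were at least 2-fold apart, 165 higher and 87 lower, over 593585 and 704872 UMIs. With the free RNA subtracted (13.1% and 30.5% of UMIs) 166 were, 81 higher and 85 lower, and without mitochondrially encoded and ribosomal protein genes 228, 121 higher and 107 lower. Of the 165 higher genes 119 were more abundant in macrophages (57 still 2-fold after subtraction) and 26 more abundant in T cells. Named genes of the T cell kind were NCR3 (10 and 69 UMIs, log2 2.24), HOXB2 (10 and 66, 2.17), MIR4435-2HG (1.90), EOMES, a transcription factor of memory CD8 cells (8 and 42, 1.81), CD40LG (11 and 51, 1.72) and CCL3 (122 and 330, 1.17). Those of the macrophage kind included CCL18 (2.72) and IGFBP2 (2.61). CD4 itself was at 2.40 (8 and 65 UMIs, 13.5 and 92.2 CPM) in these CD8 cells, against 115 and 107 CPM in macrophages. It was at 4.18 with the free RNA subtracted, so free RNA as estimated did not account for it. With only 8 exposed UMIs before subtraction, the size of that value is uncertain. Whether the deposited CD8 label holds CD4 cells was not tested. Among the lowest were HSPA6 (51 and 4 UMIs, −3.09), HSPA1B (−2.66), IFI44L (141 and 26, −2.53), MT1X (−2.44), DNAJB1 (−2.35), GADD45B (−2.29), NR4A1 (−2.28), XCL1 (−2.27), GNLY (−2.21), ERN1 (−2.16) and XCL2 (−2.14).

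Among the lists in CD8 T cells, heat stress was at −1.52 (17 members, 13 lower, percentile 0) and metallothioneins at −0.41 (8 members, 3 higher, 3 lower, percentile 0.88, and 2.98 after subtraction). T cell activation was at −0.97 over 7 members (percentile 0.02), with CD69 at −1.30, NFKBIA at −1.26, CD40LG and CD74 (1.2) higher, and at −0.18 over members with at least 50 UMIs. The cytotoxic list was at 0.29 (14 members, 4 higher, 1 lower, percentile 91.1) and at 0.54 (percentile 99.6) after subtraction, and the type 1 helper list at 0.20 (11 members, percentile 67.2), with TNF at −1.40 and IL18RAP at −1.66 (17 and 4 UMIs). The regulatory T list was at 1.09 (5 members, percentile 99.9, within the random range after thinning), with BATF at 1.09. Th17 and Th2 was at −0.70 (4 members, percentile 0.31), ribosomal protein genes at −0.36 (1.5, within the range after thinning or subtraction) and residency at −0.18 (2.48, within it by median-ratio scaling or after subtraction). Antigen presentation was at 0.64 (99.8), oxidative stress at 0.66 (99.5, within the range after thinning) and at 0 after subtraction, and the interferon list at 0.35 (94.6) and at −0.36 after it. The inhibitory receptor (−0.03), follicular (−0.02), naive (−0.05), proliferation (0.19) and mitochondrially encoded (−0.18) lists were within the range.

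Macrophages of the CBD library had more RNA of the chemokines CXCL9, CXCL10 and CXCL11, which attract T cells through CXCR3, and of guanylate-binding proteins. CXCL9 was at 13.5 CPM (12.5 to 14.5) and 138 CPM (135 to 142), 10.3-fold higher (9.52 to 11.1), CXCL10 at 31.1 CPM (29.6 to 32.6) and 174 CPM (170 to 178), 5.60-fold higher (5.31 to 5.91), and CXCL11 at 3.12 and 17.5 CPM (log2 1.47). These 3 genes lie side by side on chromosome 4 (76001275 to 76007488, 76021117 to 76023497 and 76033682 to 76041415). The transcription factor IRF1 (1.35) and GBP1 (1.37), GBP5 (1.35) and GBP4 (1.30) were higher, whereas ISG15 (−0.14), MX1 (−0.36) and IFI44L (−0.20), best known from type 1 interferon, were not. The interferon list had 21 measured members, 8 at least 2-fold higher and 0 lower, and a median of 0.75 (percentile 100). Unthinned, CXCL9 was seen in 2.69% of exposed and 41.2% of CBD macrophages, and after thinning in 0.892% (0.603 to 1.27) and 8.27% (7.28 to 9.34). In T cells it was seen, unthinned, in 0.239% and 6.94%, and after thinning in 0 of 442 exposed cells (0.679% at a floor of 3 cells) and in 5.67% (4.33 to 7.27) of CBD cells. Free RNA was estimated at 20.2% and 32.8% of macrophage UMIs, against 12.9% and 31.6% in T cells. Median UMIs were 15459.5 and 17587 per macrophage and 1521.5 and 1872 per T cell. An equal amount of free RNA per barcode would give macrophages the smaller share, so their estimate is uncertain.

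The macrophages also came from different clusters. In the exposed library 46.4% lay in cluster 1, 23.8% in cluster 2 and 19.3% in cluster 4, and in the CBD library 48.5% in cluster 11, 32.9% in cluster 7 and 15.9% in cluster 10, each mostly of that library and so possibly the library rather than a type. CXCL9 and CXCL10 were among the leading genes of cluster 7, which was monocyte-derived macrophage-like. That class held 84 exposed and 941 CBD cells, but 364 and 0 with each library clustered alone, so its order between the libraries is not settled. Without that cluster, CXCL9 was at log2 1.30, CXCL10 at 0.60 and the interferon list at 0.54.

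**Figure D4:**
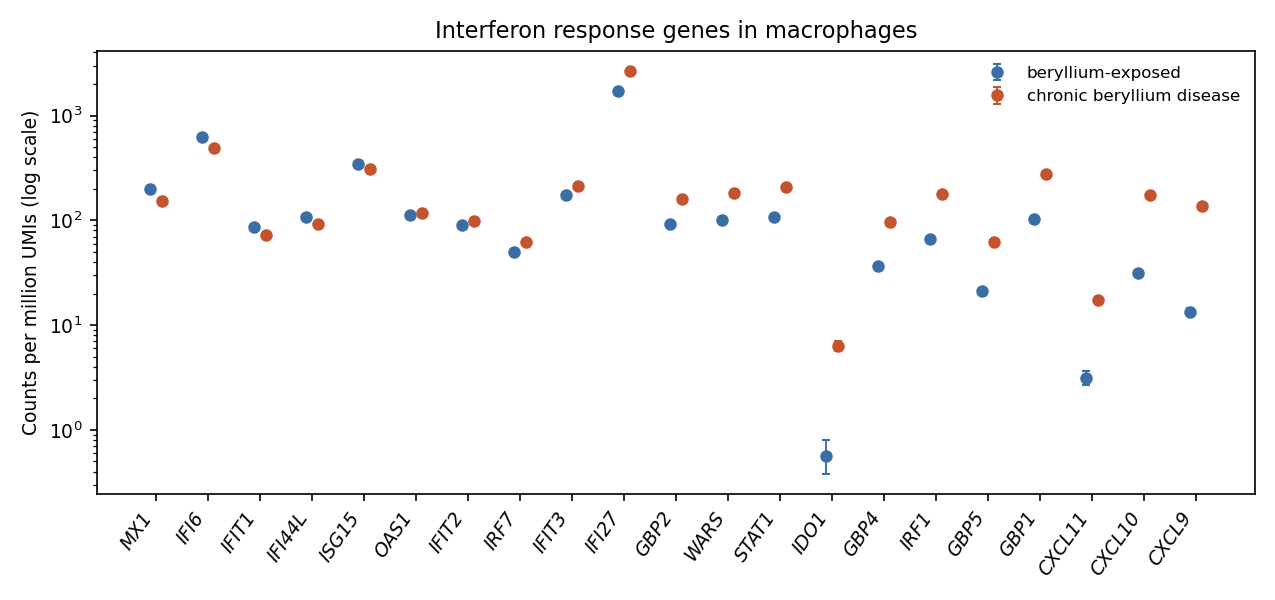
Points give CPM (log scale) of the 21 interferon list genes in macrophages of the exposed (blue) and CBD (orange) library, with 95% Poisson intervals, ordered by their log2 difference. MX1 was lowest at −0.36 and CXCL9 highest at 2.96.

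Of 2521 genes past the limit in macrophages, 78 were at least 2-fold apart, 43 higher and 35 lower, over 53175889 and 49003927 UMIs. By median-ratio scaling, which moved all genes by −0.15 on the log2 scale, 76 were, 28 higher and 48 lower, and without cluster 7 there were 62, 24 higher and 38 lower. The membrane protein gene TMEM176B was at 2.37 CPM (1.97 to 2.82) and 79.6 CPM (77.1 to 82.1), 33.6-fold higher (28.1 to 40.4), the calcium-binding S100A1 at 3.16 and 65.1 CPM, 20.6-fold (17.6 to 24.2), C15orf48 8.55-fold and the amyloid precursor APP 8.92-fold. VAMP5 (log2 2.22), METTL9 (1.79), NQO2 (1.78), the MAP kinase phosphatase DUSP6 (1.75), the aminopeptidase ANPEP (1.72) and RNASE1 (1.70, and 0.25 without cluster 7) were higher. The aldo-keto reductase AKR1C1 was 15.9-fold lower (50.5 and 3.18 CPM, 13.5 to 18.8), and HPGDS, the prostaglandin D synthase, 11.0-fold lower (58.3 and 5.29 CPM, 9.71 to 12.6). ZNF331 (−1.87), MT-ATP8 (−1.56), ACOT2 (−1.5), the transglutaminase TGM2 (−1.47), RND3 (−1.47), THBS1 (−1.47), MT-ND4L (−1.46), ACKR3 (−1.46) and the growth factor HBEGF (−1.43) were lower.

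The antigen presentation list had a median of 0.41 in CBD macrophages (16 members, percentile 100), with TAP1 at log2 1.03, PSMB9 at 0.99, LGMN at 0.94, CIITA at 0.48, B2M at 0.44, CD74 at −0.32 and HLA-DRA at −0.44. The inflammatory list was at 0.35 (16 members, percentile 100), with TNF 3.17-fold higher (1.38), CCL3 at 0.96, IL1B at 0.34 and CXCL2 and CXCL3 both at −0.64. The monocyte-derived list was at 0.31 (17 members, percentile 100), with CCL18 (1.35), S100A8 (1.16) and VCAN (1.03) higher and TREM2 (−1.13) lower. Without cluster 7 these lists were at 0.31, 0.12 (percentile 75.5) and 0.13 (96.3). Alveolar macrophage identity genes were at 0.07 (18 members, percentile 84.5), with FABP4 at 0.19, MARCO at 0.10, CES1 at 1.36, HBEGF at −1.43 and the transferrin receptor TFRC at −1.33. Lipid handling was at 0.11 (18 members, 86.7), with LIPA at −0.85, and the granuloma list at 0.05 (17 members, 55.1), with CHIT1 (14 and 113 UMIs) and CHI3L1 (14 and 148 UMIs) few in both libraries. Oxidative stress was at 0.09 (16 members, 72.6), with TXN at 1.05, and proliferation at 0.04 (16 members, 26.8). By median-ratio scaling these 5 medians turned negative, to −0.07, −0.04, −0.08, −0.01 and −0.04.

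Metallothioneins were lower in CBD macrophages as well, with MT1G at −1.39, MT1E at −1.18 and MT2A at −0.43, and a list median of −0.18 (15 members, 2 lower, 0 higher, percentile 0.05). Cluster 3, led by metallothionein genes, held 267 exposed and 58 CBD barcodes. Mitochondrially encoded genes were at −0.53 (10 members, percentile 0), with MT-CO2 at −1.0, beside median mitochondrial shares of 9.58% and 6.48% of UMIs. Heat stress genes were at 0.21 (17 members, 1 higher, 1 lower, percentile 99.6), ribosomal protein genes at −0.10 (16 members, percentile 2.06, within the range after thinning) and the red cell list at 1.73 (3 members, all higher). Across the 14 lists measured in macrophages, 6 medians lay above and 3 below the random range.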

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

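All tests of the heat stress pattern were chosen after that pattern was seen, and the bounds of those by thinning and mitochondrial share were written before the values of these tests were computed. The difference between CBD and exposed library went opposite ways in 2 classes for heat shock and immediate early genes, with medians of −1.46 in T cells and 0.21 in macrophages, and for the T cell activation list, with 0.58 in CD4 and −0.97 in CD8 T cells. Neither difference between classes was tested, since each library is 1 sample. In the activation list both medians rest on few members, and over members with at least 50 UMIs they were −0.10 and −0.18. The unnamed minor cluster held 86 UMIs of MS4A1 and 148 of CD79A, B cell genes, in the CBD library and at most 3 of each in the exposed one.

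Lower heat stress RNA in T cells may come from handling, from depth, from damaged cells or from a difference between the people. A handling effect that moved every cell type alike is not what the macrophages show, where the list was at 0.21 with members going both ways. That value is part of the pattern as flagged, so it is no separate test. Different depth is argued against by thinning, after which the T cell list was still at −1.46. Among T cells under 10% mitochondrially encoded UMIs the list was at −1.56, so cells with a high mitochondrial share do not account for the pattern. NK cells, 31 and 80 in number, were at −1.35, so a handling effect on lymphocytes alone stays open. So does a biological difference between the groups, which was not tested.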

How the results depend on the processing

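The alternatives that remove high doublet scores, cluster 7 and cells over 5000 UMIs, and the list settings with free RNA subtracted, thinned or under 10% mitochondrially encoded UMIs, were chosen after the main results were seen. The planned setting with doublets kept equals the main one, since none were removed. No paired analysis was possible because each group is 1 library. For the values below the cause was not tested. T cells were 21.8% (exposed) and 35.1% (CBD) from clusters and markers alone, 19.2% and 30.7% without the highest doublet scores, and 22.8% (exposed) under 10% mitochondrially encoded UMIs. Macrophages were 74.5% and 60.0% at resolution 0.5, 69.2% and 64.4% under 10%, 75.7% and 63.4% with at least 1000 UMIs and 500 genes, 71.6% (exposed) without the highest doublet scores and 55.7% (CBD) with each library clustered alone. CD4 and regulatory T cells were 58.5% and CD8 41.5% of exposed T cells under 10%. By CD4 against CD8A and CD8B UMIs they were 15.9% and 84.1% (exposed) and 62% and 38% (CBD). Each pair kept its order between libraries. Genes at least 2-fold apart were 145 in T, 129 in CD4, 138 in CD8 T cells and 42 in macrophages with 100 UMIs and 100 CPM, and 1226, 1294, 878 and 1292 with 20 UMIs over both libraries alone. In CD8 T cells there were 166 with free RNA subtracted. The interferon list in T cells was at −0.20 with free RNA subtracted, and 6 lists in CD4 T cells were outside the random range over members with 50 UMIs. Of the remaining values, 83 for the main comparisons were within their limits, as were 542 others, while 31 moved, 34 list medians came inside the random range and 13 went outside it. Thinning to 1000 UMIs gave 26 of the 31. Depth limits genes under 20 UMIs over both libraries, which entered no list, and classes of few cells such as NK cells.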

Other observations

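All tests in this part were chosen after the patterns were seen, and those of free RNA with genes chosen alike in both libraries, of interferon genes without cluster 7, of type 1 interferon members and of IFNG also after their own values were seen. NK cells, 31 exposed and 80 CBD, with 45025 and 159838 UMIs in all, shared the lower heat stress RNA of T cells, with HSPA1B at log2 −3.03 (27 and 11 UMIs), DNAJB1 at −2.93 and HSPA6 at 30 and 0 UMIs, and 10 of 14 list members at least 2-fold lower. Of T cell markers in these NK cells, TRBC2 was at 400 and 125 CPM (18 and 20 UMIs), TRAC at 178 and 125 and CD2 at 422 and 413. The share of T cell RNA in these barcodes was not estimated. MT2A was at −2.50 (44 and 27 UMIs) in NK cells, while FTH1 (1.31) and FTL (1.08) were higher, and the metallothionein list of 4 members had a median of 0.67. GNLY, far lower in CBD T cells, was at a ratio of 1.18 (1.03 to 1.35) in NK cells (257 and 1073 UMIs), and the cytotoxic list of 11 members had a median of −0.48 with 1 member lower.

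Dendritic-like cells, 38 and 69 in number, had 131 and 206 UMIs of CLEC9A, a marker of cross-presenting dendritic cells, among 271004 and 499630. Of genes of mature dendritic cells, CCL22 had 94 and 30, LAMP3 68 and 29, CCR7 70 and 34 and FSCN1 53 and 55 UMIs, and all 4 lead cluster 14, which held only 11 exposed and 5 CBD cells. The unnamed minor cluster had 208 and 10 UMIs of FCER1A among 364548 and 211728. Globin transcripts were seen in CBD macrophages, HBB with 0 and 1230 UMIs, HBA2 with 0 and 569 and HBA1 with 0 and 327. HBB lay in 195 of the CBD macrophages (6.81%), against 967 if its UMIs were spread evenly, and 1058 of them were in 34 cells of cluster 10. HBA1 and HBA2 are nearly identical, so their split is uncertain.

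Many macrophage genes were higher in CBD T cells, and free RNA is a candidate explanation. Over 35 genes at least 10 times more abundant in exposed macrophages, the log2 difference in T cells minus that in macrophages had a median of 1.65 (quartiles 1.47 to 1.76) against 1.29 set by the free RNA shares, which missed the bound of 0.3 written beforehand, but a minimum of 10 lies above 7.74, the ratio free RNA alone gives in the exposed library, so it picks genes low in exposed T cells. Over 280 genes chosen alike in both libraries, with 4, the only other minimum tried here, the median was 1.41 (1.16 to 1.73). Of the 162 genes of the pattern, 52 stayed at least 2-fold higher after subtraction. On the same measure these 52 had a median of 1.34 (quartiles 1.11 to 1.48) and all 162 one of 1.31, both near 1.29. The 52 thus did not depart from free RNA by this measure. Both sets were chosen for being higher in CBD T cells, so this is no independent test, and another cause stays open. The 5% of CBD T cells richest in macrophage markers held 6.0% of the UMIs of these markers, where an even spread gives 6.39%. The markers were thus not concentrated in a few cells. Listed CBD cells had at most 5846 UMIs, against a median of 17587 in CBD macrophages. A barcode with a whole macrophage was thus unlikely to be among them, so the test says little on joined T cells and macrophages. For the genes more abundant in T cells 100% (15 of 15) stayed at least 2-fold higher after subtraction, which decides nothing because the subtraction raised all 15, and a difference between the people was not tested.

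Higher interferon genes in CBD macrophages may come from more monocyte-like cells, from depth or from a response to interferon. After thinning, the list was at 0.80. Random thinning keeps each gene's expected share of a cell's UMIs, so the median could hardly have moved, and depth stays open. More monocyte-like cells stay open as well. Without cluster 7 the list was at 0.54. The monocyte-derived class held 84 and 941 cells, or 364 and 0 with each library clustered alone. The 10 members best known from type 1 interferon had a median of −0.027, so these members did not share the difference. The other 11 were at 1.35, and at 0.71 without cluster 7 (8 and 3 members at least 2-fold higher). The members were split after the values were seen, so this is no independent test against type 1 interferon. A higher CPM of IFNG in T cells stays open as well, since its ratio was 0.948 (0.863 to 1.04) but log2 0.24 after free RNA subtraction. Over the whole library, where T cells were more numerous in the CBD one, IFNG was at 13.5 CPM (12.6 to 14.5) and 33.9 CPM (32.4 to 35.5), which says nothing of its level per T cell UMI, and a response to interferon gamma from the larger number of T cells stays open as a hypothesis, untested with 1 library per group.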
